A study of Arabidopsis thaliana with 21 samples.

How the data were processed

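RNA of 7-day-old Arabidopsis thaliana seedlings was measured on 21 single-colour Affymetrix ATH1 arrays, 3 for each of 7 groups. Wild type (Col-0, written WT) was sampled in growth light (LL, continuous white light of 100 µmol quanta per m2 per s), after 3 h of high light (HL, 1000 µmol quanta per m2 per s) and after 3 h of blue light (BL, the same type of lamp behind a filter passing 400 to 540 nm). The cry1 mutant, which lacks the blue light receptor cryptochrome 1, and the hy5 mutant, which lacks the light signalling transcription factor HY5, were sampled in LL and HL. The labels describe the 3 arrays of a group as biological triplicates and letter them A, B and C. The photon flux in blue light is not given in the sources used here.

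The deposited values are 1 intensity per probe set and array, made by the authors with GCOS 1.1 and GCRMA, per the submitters' processing notes. GCRMA corrects the background from probe sequence, normalizes between arrays and summarises the probes of a probe set. The software that ran it and its settings are not given in the sources used here. The deposited intensity is on a linear scale, running from 0.0313 to 18828.3, with array medians from 65.8 to 79.8. Of all values, 3.51% lay under 1. A fold against a group near that level therefore depends on the background correction and on the floor set here, and the number of arrays limits the precision of every value.

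Intensities were set to at least 1 and log2 transformed. The 64 control probe sets of the 22810 in the table were left out, and the 16289 of the other 22746 with log2 of at least 5 in at least 3 arrays were kept. Group means were fitted over all 21 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, 14 residual and 2.88 prior degrees of freedom). Each of 11 contrasts was adjusted by Benjamini-Hochberg over the kept probe sets, and a probe set was called at an adjusted p under 0.05. Every adjusted p for a gene is from this limma fit, errors of changes are standard errors (SE), and group levels are log2 means with the SD of n = 3 arrays. An interaction is the HL minus LL change of a mutant minus that of WT. A CRY1- or HY5-dependent high light gene was at least 2-fold changed and called in WT, with a called interaction of opposite sign. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

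Genes were named from the platform annotation, with symbols updated by gene identifier through a RefSeq gene table. Of the 16289 kept probe sets, 8858 had 1 gene, 346 had several and 7085 had none listed. Probe sets with several genes or none are counted and not named, apart from those singled out below after their values were seen. No probe set was listed for CRY1, HY5, COP1, CHS, ELIP1, ELIP2 or APX2, so the targeted genes could not be used to check the genotype labels.

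Before the data were examined, the design, the alternatives, 18 gene lists and a rule for named genes were fixed. For the 2 main WT comparisons and the interactions the rule takes the 8 largest called rises and falls among single genes, where all 9 differences between arrays have 1 sign. For the genotype comparisons within a light it takes 4 each way, and from each list at most 4 called members, or 2 as values where none is called. HYH is always named. Of 323 list members 51 were measured. The lists of general phenylpropanoid enzymes, flavonoid regulators, jasmonate and wounding genes and seed storage markers had no measured member, and 6 others had 1 or 2, for which member values alone are given. The 8 lists with at least 3 members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, with an estimated correlation beside it. The brightest probe set stood for a gene.

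The steps were tested on simulated data with the means and spreads of the kept 16289 probe sets, 100 of them changed by log2 1 and 100 by log2 2. For WT in HL against LL, 67% of changes of log2 1 and 89% of changes of log2 2 were recovered, with 13 false calls. For the cry1 interaction the shares were 39% and 79%, with 8 false calls. The simulated noise was independent between probe sets. These shares may therefore be too high for arrays with a common structure, or where fewer probe sets change. A flavonoid list shifted by log2 1 was called and none of the other 7 lists was.

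The title of array B of cry1 in LL names the control light, whereas its source name speaks of blue light. It was kept in the LL group by its title. On a score of genes at least 2-fold changed in BL and different from HL, it lay at -0.44, with the other cry1 LL arrays at -0.18 and -0.69 and the WT BL arrays between 2.46 and 2.95. This does not settle the label, since the score comes from WT and a cry1 sample in blue light could score low too. Alternatives were other filters, trend and robust priors, array weights, a repeated quantile normalization, median centring, fits of the compared groups alone, a replicate block, leaving out each array, a stricter threshold, other selections of dependent genes, other list tests and, added after the data were seen, log2 of the intensity plus 16 and the high light score without each array.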

Results

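Transcript levels of 16289 probe sets were compared between 7 groups of 3 arrays each. Wild type seedlings (WT) were measured in growth light (LL), after 3 h of high light (HL) and after 3 h of blue light (BL), and the cry1 and hy5 mutants in LL and HL. Arrays correlated at r between 0.872 and 0.976 across probe sets. The first principal component held 30.5% of the variance and parted HL from LL arrays. The second, with 16.1%, set apart the WT BL arrays at -60.33 to -51.01 and, at its other end, the hy5 arrays at 20.47 to 30.53. The WT and cry1 arrays in LL and HL lay between -13.46 and 14.17 on it. Array C of cry1 in HL lay at 9.16 on the first component, whereas the other 8 HL arrays lay between 35.39 and 47.09 and the LL arrays between -42.94 and -30.69. The third component, with 12.6%, did not follow the groups alone: it lay between 17.32 and 36.39 in WT LL array C, WT HL array A, cry1 LL arrays B and C and the 3 cry1 HL arrays, and between 0.14 and 6.29 in the other WT LL and HL arrays and cry1 LL array A. The hy5 arrays lay between -32.49 and -21.96 on it and the WT BL arrays between -24.24 and -11.20.

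What high light does to the wild type seedling was asked first. After 3 h of HL, genes of anthocyanin synthesis, heat shock proteins and cold- and dehydration-induced genes rose, and genes of chlorophyll synthesis fell. UGT76E12, a UDP-glycosyltransferase, rose by 7.36 ± 0.94 (SE) on the log2 scale, from 1.63 ± 1.56 in LL to 8.98 ± 0.28 in HL (SD, n = 3). LEA4-5, a late embryogenesis abundant protein, rose by 6.48 ± 0.87, and PUB19, a U-box ubiquitin ligase, by 6.38 ± 0.86. The expansin gene EXPA8, whose product loosens cell walls, fell by 3.65 ± 0.46, from 8.58 ± 0.65 to 4.92 ± 0.57.

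Among 16289 probe sets, 1269 rose and 1385 fell at a limma adjusted p under 0.05, and of these 638 rose and 354 fell at least 2-fold. The other named rises were AT5G53710, AT1G71000, AT1G09500, AT5G50360 and UGT73C1, with log2 changes from 7.26 down to 5.23. All 8 had log2 means under 4 in LL, between 1.05 and 3.94, so that their folds depend on the background level. The other named falls were AT5G05250, AT5G61590, UGT85A4, AT1G19960, AT1G25230, TBL45 and AT5G16030, AT5G61590 at -3.25 and TBL45 at -2.97 among them.

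All 8 measured flavonoid and anthocyanin enzymes rose in HL, also when adjusted over the list alone. UF3GT rose by 1.98, AT4G14090 by 1.95, CHIL by 1.81 and UGT78D2 by 1.80, and the list moved up against the other probe sets (camera adjusted p = 2.64e-13, and adjusted p = 0.00357 with an estimated correlation). Of 6 heat shock genes 5 rose, and all 6 when adjusted over the list alone. AT1G53540 rose by 4.06, AT5G51440 by 2.90 and AT5G48570 by 2.33 (camera adjusted p = 4.99e-06, and adjusted p = 0.0272 with an estimated correlation). Array A was the highest WT HL array for each measured heat shock gene. AT1G53540 lay at 10.198 in it and at 6.195 and 7.262 in arrays B and C, so the size of its rise is uncertain. The 3 measured cold and abscisic acid genes rose, COR15A by 4.16, COR15B by 3.16 and COR47 by 1.51 (camera adjusted p = 7.71e-05, and adjusted p = 0.0298 with an estimated correlation), and all 3 were called when adjusted over the list alone. Of 6 chlorophyll synthesis genes 4 fell, over the list alone too (camera adjusted p = 0.00319, and adjusted p = 0.0239 with an estimated correlation), with PORB, which reduces protochlorophyllide in the light, down by 1.52.

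Other lists moved less or were small. Of 7 reactive oxygen and antioxidant genes 3 rose and 1 fell, with 4 called when adjusted over the list alone and no shift of the list (camera adjusted p = 0.0615). STZ, a zinc finger factor, rose by 3.09, the glutathione reductase gene GR1 by 1.03 and the stromal ascorbate peroxidase SAPX by 0.76, while the thylakoid form TAPX fell by 0.47. Of 3 antenna genes LHCB4.2 fell by 1.29, with 2 called when adjusted over the list alone (camera adjusted p = 0.106), and of 7 photosystem and Calvin cycle genes PRK fell by 0.32, with 2 called when adjusted over the list alone (camera adjusted p = 0.0694). The clock gene GI rose by 1.00, APL3, a subunit of the starch synthesis enzyme ADP-glucose pyrophosphorylase, by 2.57, and HYH, the closest homolog of HY5, by 1.71 ± 0.25. No auxin and shade gene of 3 was called, GH3.3 lying at 0.83 and IAA29 at -0.39, and the list was not shifted. Neither root marker was called (EXPA18 at -0.32, EXPA7 at -0.03), nor were the sulfite reductase SIR at -0.16 or the photoprotection genes LIL3:1 and LYC, both at -0.23. The count of 2654 called probe sets fell to 1691 when the 2 groups were fitted alone and to 1496 at an adjusted p under 0.01.

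Blue light was given to the wild type alone. The measured flavonoid enzymes, cold genes and auxin and shade genes of the fixed lists rose. COR15A rose by 4.09 ± 0.65, and GH3.3, whose product conjugates auxin to amino acids, by 3.61 ± 0.44, from 6.59 ± 0.76 in LL to 10.21 ± 0.42 in BL (SD, n = 3). AT1G33055 fell by 4.54 ± 0.47 and AT4G27450 fell by 3.15 ± 0.46.

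At a limma adjusted p under 0.05, 1210 probe sets rose and 2180 fell in BL, of which 363 and 600 changed at least 2-fold. The median change of all kept probe sets was -0.09 log2, and after centring each array on its median 2123 rose and 1300 fell, so that the balance of rises and falls depends on the scaling. After a repeated quantile normalization 1343 rose and 1531 fell. The other named rises were UGT73C1, PUB19, AT1G51090, UGT84A1, LEA4-5 and COR15B, by 4.49 to 3.35, and the other named falls AT4G39675, AT3G05170, NAMT1, AT1G69080, AT5G61590 and AT5G59080, with log2 changes from -4.08 to -3.11. NAMT1 and AT3G05170 fell to means of 0.08 and 0.96, at the floor.

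All 8 flavonoid enzymes rose in BL, over the list alone too, with CHIL up by 2.27, AT1G06000 by 2.24 and UGT78D2 by 2.23 (camera adjusted p = 1.28e-12, and adjusted p = 0.00454 with an estimated correlation). The 3 auxin and shade genes rose, among them IAA29 by 3.16, with 3 called when adjusted over the list alone (camera adjusted p = 0.000319, and adjusted p = 0.00542 with an estimated correlation). The 3 cold and abscisic acid genes rose and were called over the list alone (camera adjusted p = 0.000336), but the shift of the list was lost with an estimated correlation (adjusted p = 0.0623). Of 7 reactive oxygen genes 2 rose, SAPX by 0.78 and GR1 by 0.62, the same number as when adjusted over the list alone (camera adjusted p = 0.0142, lost with an estimated correlation at adjusted p = 0.104). Of 6 heat shock genes 2 fell, AT5G51440 and AT5G48570, over the list alone too, without a shift of the list (camera adjusted p = 0.289). The call of AT5G48570 was lost without WT BL array B or C. HYH rose by 1.96 ± 0.25 and APL3 by 2.06, LHCB4.2 fell by 0.76, and GI at 0.04 was not called. The total of 3390 fell to 2011 with the 2 groups fitted alone and to 1635 at an adjusted p under 0.01.

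**Figure D1:**
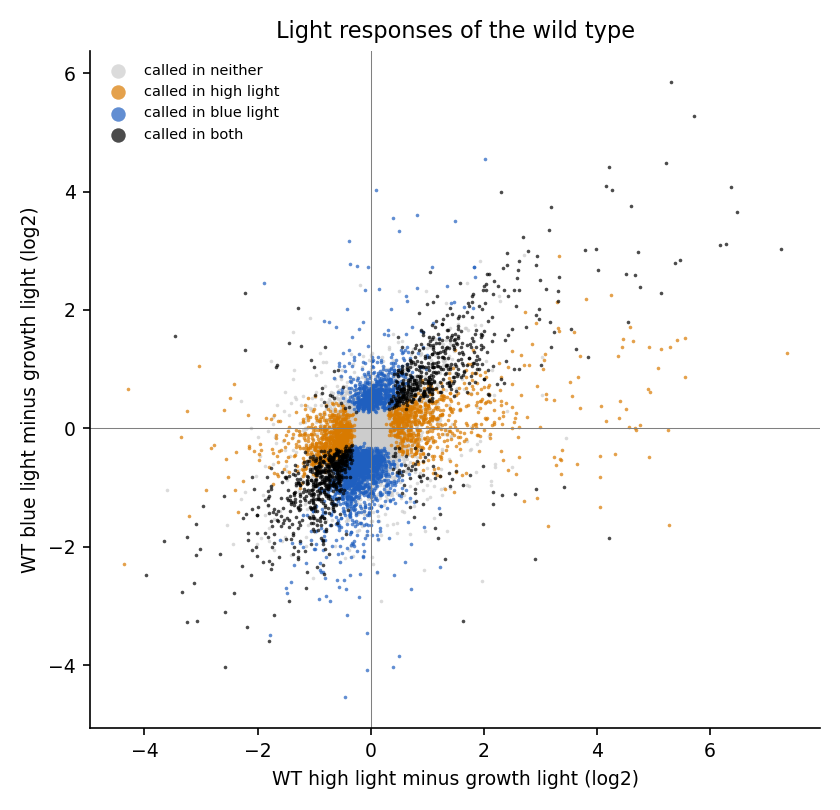
Log2 change of each of the 16289 probe sets in wild type after high light (x axis) and after blue light (y axis), both against the same 3 growth light arrays; colours show in which of the 2 comparisons a probe set was called. Of those called in both, 486 rose in both and 592 fell in both.

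High light and blue light were then set against each other in the wild type. Heat shock genes were higher in HL than in BL, and auxin and shade genes were lower. All 6 heat shock genes were called, over the list alone too, with AT5G51440 higher in HL by 5.10 and AT1G53540 by 4.88 (camera adjusted p = 6.19e-06, and adjusted p = 0.0243 with an estimated correlation). IAA29 was lower in HL than in BL by a log2 difference of -3.56, GH3.3 by -2.78 and WES1 by -1.20, 3 of 3 also when adjusted over the list alone (camera adjusted p = 0.000917, and adjusted p = 0.0182 with an estimated correlation). Of 6 chlorophyll synthesis genes 3 were lower in HL, over the list alone too, among them PORB by -1.20 and CHLI2 by -0.80 (camera adjusted p = 0.00487, and adjusted p = 0.0243 with an estimated correlation). Flavonoid enzymes differed in both directions, UF3GT being higher in HL by 0.90 and AT1G06000 lower at -1.07, with 2 called when adjusted over the list alone and no shift (median 0.02, camera direction down, camera adjusted p = 0.79). Photosystem and Calvin cycle genes shifted down (2 of 7 called, 4 over the list alone, camera adjusted p = 0.00561), which was lost with an estimated correlation (adjusted p = 0.26). GI was higher in HL by 0.97, and HYH at -0.26 was not called.

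In all, 1944 probe sets were higher and 1459 lower in HL than in BL, 648 and 237 of them at least 2-fold. After median centring 1444 were higher and 2308 lower, so that this balance turned with the scaling. The total of 3403 was 1922 with the 2 groups fitted alone, 1602 at an adjusted p under 0.01, and 2137 without WT HL array A.

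Of the probe sets called in HL and in BL, 486 rose and 592 fell in both and 89 moved in opposite directions. Independent lists of these sizes would share 94.3 rises and 185.4 falls, and simulated unchanged groups set against the same LL arrays share 387.1 and 592.2 among equally long top lists. Those simulated comparisons had 0 and 0.15 calls on average over 20 simulations, so their top lists are ranked noise, unlike lists of calls. Part of the sharing may still come from the common controls, in a share that these numbers do not give. The log2 changes correlated at r = 0.5, no more than the 0.504 that shared controls alone gave in the simulation, while their covariance was 0.192 against 0.0432. Of the opposite ones, 63 rose in HL and fell in BL and 26 did the reverse. With the difference between HL and BL itself called, 486 probe sets rose in HL and were not called in BL, and 454 rose in BL and were not called in HL. Among the falls these numbers were 381 for HL and 768 for BL.

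The cry1 mutant was compared with the wild type to ask what cryptochrome 1 contributes. In LL few probe sets were called, though 1327 had an unadjusted p under 0.05 in the limma fit, so that a small difference is not shown. AT1G75280 was lower in cry1 by a log2 difference of -6.89 ± 0.83, at 4.26 ± 1.42 against 11.15 ± 0.33 in WT (SD, n = 3), and AT1G75300 by -3.83 ± 0.67. In HL the same genes were lower by -8.76 and -3.44, and ATG8D, which encodes an autophagy protein, was lower in LL by -1.68 ± 0.16 and in HL by -1.52 ± 0.16. EXPA8 was higher in cry1 in HL by 2.09 ± 0.46 and AT2G23910 lower by -1.86 ± 0.23.

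The third principal component ran partly along this contrast, being at 17.32 or above in the cry1 arrays other than LL array A and, among WT, in LL array C and HL array A. In LL 4 probe sets were higher and 10 lower in cry1 at a limma adjusted p under 0.05. Of the 5 that were lower by at least 4-fold 3 have no listed gene, as have 9 of 11 in HL. The fourth named fall was AT5G62200 at -0.82, and none of the 4 rises met the rule for names. No member of a fixed list was called in LL, 3 flavonoid enzymes being called when adjusted over the list alone, and HYH differed by -0.14. The photosystem and Calvin cycle list shifted up in LL (median 0.17, camera adjusted p = 0.0206), which was lost with an estimated correlation (adjusted p = 0.267). The count of 14 became 9 without WT LL array A or B, 27 without array C, 61 with array weights, 7 at an adjusted p under 0.01 and 0 with the 2 groups fitted alone. The call of AT1G75300 in LL was lost when array A, B or C of WT, or A or C of cry1, was left out.

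In HL 80 probe sets were higher and 78 lower in cry1 than in WT, 37 and 31 of them at least 2-fold. Further named rises were AT3G06160, AT2G15560 and AT1G43590, by 3.04 to 2.21. In WT HL these lay at 2.69 ± 1.58, 1.98 ± 1.73 and 3.83 ± 0.44 (SD, n = 3), so that their folds depend on the background level. Of the flavonoid enzymes AT1G06000 was lower by -0.82 and called, 4 were called when adjusted over the list alone, and the list had a median of -0.42 (camera adjusted p = 1.85e-06), a shift lost with an estimated correlation (adjusted p = 0.0619). LHCB4.2 was higher by 0.78 and was the 1 antenna gene of 3 called, over the list alone too. HYH differed by -1.01 ± 0.25 and was not called (adjusted p = 0.0707), though it was called with array weights, trend and robust priors, a filter at log2 7 or log2 of the intensity plus 16, the last added after the data were seen. The photosystem list (camera adjusted p = 0.0162) and the auxin and shade list (camera adjusted p = 0.0472) shifted up, and both shifts were lost with an estimated correlation (adjusted p = 0.288 and 0.125). The count of 158 was 46 without WT HL array B, 92 without array C, 65 without cry1 HL array A, 53 without array C and 169 without array B. It was 101 without a filter, 373 with array weights, 47 at an adjusted p under 0.01 and 8 with the 2 groups fitted alone. The calls of AT3G06160, AT2G15560, EXPA8, AT1G75300, AT1G06000 and LHCB4.2 were each lost without cry1 HL array C and without at least 2 others of the 6 arrays.

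Within cry1, flavonoid, heat shock and cold genes rose in HL and chlorophyll synthesis genes fell. All 8 flavonoid enzymes rose, over the list alone too, with AT4G14090 up by 1.38 and UGT78D2 by 1.25 (camera adjusted p = 9.56e-11, and adjusted p = 0.00544 with an estimated correlation). Of 6 heat shock genes 5 rose and all 6 were called over the list alone (camera adjusted p = 9.09e-07, and adjusted p = 0.0183 with an estimated correlation). The 3 cold genes rose (camera adjusted p = 4.4e-05, and adjusted p = 0.0253 with an estimated correlation), and 4 of 6 chlorophyll synthesis genes fell, PORB by 1.43 (camera adjusted p = 0.000203, and adjusted p = 0.00544 with an estimated correlation). Of 7 reactive oxygen genes 3 rose, over the list alone too (camera adjusted p = 0.0493, lost with an estimated correlation at adjusted p = 0.147). HYH rose by 0.83 ± 0.25, a call lost without cry1 LL array B or C or cry1 HL array A or B. In all 993 probe sets rose and 770 fell, 497 and 179 at least 2-fold. The total of 1763 was 977 without cry1 HL array A, 1005 without array B, 1977 without array C, 808 at an adjusted p under 0.01 and 466 with the 2 groups fitted alone.

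The difference of the HL responses between cry1 and WT, which tests the dependence on CRY1 itself, was called for 1 probe set of 16289. In the limma fit 702 had an unadjusted p under 0.05, fewer than that threshold gives on average without any difference. The called probe set has no gene listed and is given here after its values were seen. Its level rose in WT from 4.66 ± 0.12 in LL to 9.26 ± 0.29 in HL (SD, n = 3), and reached 6.86 ± 0.32 in cry1 in HL. The interaction was -2.52 ± 0.36 (adjusted p = 0.0378), and it was the 1 CRY1-dependent gene among the 992 probe sets that changed at least 2-fold in WT HL. The call was lost when any of WT LL arrays A, B and C, WT HL arrays A and B, cry1 LL array C or cry1 HL arrays A and B was left out, without a filter, with a repeated quantile normalization, with the replicate block (adjusted p = 0.153), at an adjusted p under 0.01 and with cry1 and WT groups fitted alone. The call was also lost when any hy5 array was left out, since these arrays enter the residual variance shared by all groups. The responses of the 8 flavonoid enzymes were smaller in cry1 by a median of -0.57, with no member called and 1 called when adjusted over the list alone. The list shifted down (camera adjusted p = 8.79e-06), which was lost with an estimated correlation (adjusted p = 0.0884). HYH had an interaction of -0.88 ± 0.35 (adjusted p = 0.999).

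A score over HL genes selected in hy5 gave the size of the response. The score is the mean log2 level of 685 probe sets that rose at least 2-fold in hy5 HL minus that of 463 that fell. The set was chosen by the hy5 levels, the cry1 and WT arrays entering only through the shared residual variance. The score rose by 2.88 in WT and by 2.37 in cry1 from LL to HL, a difference of -0.50 (exact permutation test of genotype within light, two-sided, p = 0.24 over 400 regroupings). These regroupings are exact only where genotype has no effect in either light. A difference present in both lights can widen their spread, so a large p does not show equal responses. Without cry1 HL array C, left out after its value was seen, the rise in cry1 was 2.65 and the difference -0.23 (exact permutation p = 0.36 over 200 regroupings), so that more of the difference rested on this array than on any other; without each other array it lay between -0.65 and -0.44. In HL alone the cry1 arrays scored 1.02 ± 0.48 and the WT arrays 1.68 ± 0.12 (SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 allows). Array C of cry1 scored 0.466 and arrays A and B 1.291 and 1.301. Over the same probe sets the median change of the rises was 1.41 in WT and 1.24 in cry1, and that of the falls -1.04 and -0.80.

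**Figure D2:**
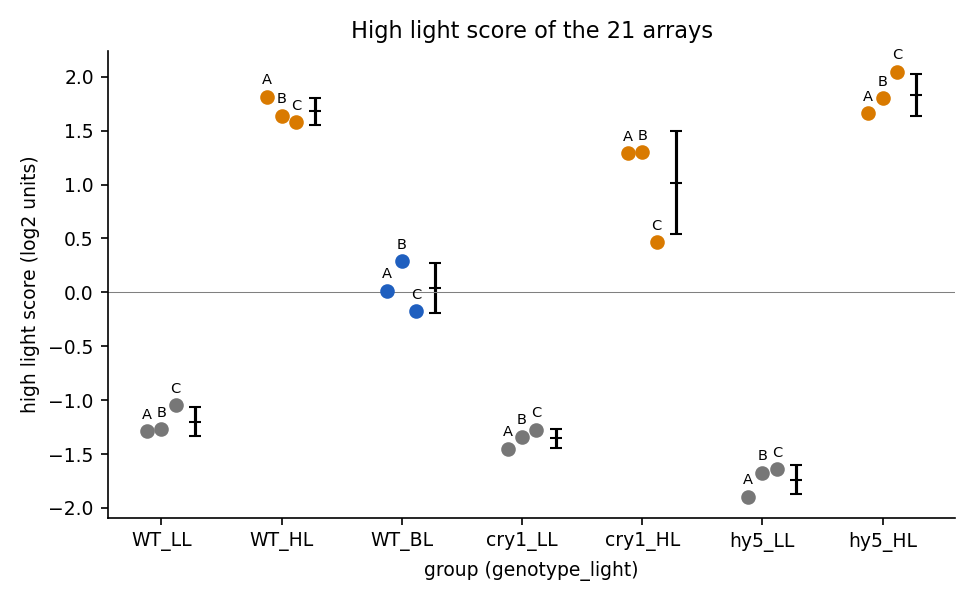
High light score of each array (log2 units; points are arrays with their replicate letters, bars the mean and SD of 3 arrays), by group. The cry1 HL arrays A and B at 1.291 and 1.301 and C at 0.466 lie below the lowest WT HL array at 1.58, and the LL arrays lie between -1.90 and -1.05; hy5 arrays chose the probe sets, so their own scores are not independent of it.

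The hy5 mutant was compared with the wild type in the same way. Flavonoid and anthocyanin enzymes were lower in hy5 in both lights. In LL CHIL was lower by -1.86, DFR, which makes leucoanthocyanidins, by -1.90 and AT4G14090 by -2.01, and in HL AT4G14090 was lower by -2.38 and AT5MAT, an anthocyanin acyltransferase gene, by -2.15. In LL 7 of 8 enzymes were lower and 8 when adjusted over the list alone (camera adjusted p = 3.47e-19, and adjusted p = 0.000606 with an estimated correlation), and in HL 8 of 8 by both (camera adjusted p = 1.61e-21, and adjusted p = 0.000334 with an estimated correlation). HYH was lower in LL by -1.69 ± 0.25 and differed in HL by -0.73 ± 0.25 without a call, which it gained with the 2 groups fitted alone or with log2 of the intensity plus 16.

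In LL 198 probe sets were higher and 457 lower in hy5 at a limma adjusted p under 0.05, 85 and 237 of them at least 2-fold. The named falls were AT5G23830 at -6.58 ± 0.47, the ubiquitin ligase gene LUL1 at -5.40, CSA1, which encodes a disease resistance type protein, at -4.70, and AT1G12010 at -4.66. Their hy5 LL means lay between 1.49 for LUL1 and 2.38 for AT5G23830, so that the sizes of these falls depend on the background level. The named rises were AT5G24240 at 6.25 ± 0.43, AT1G10110, AT5G15360 and AT5G44440, from WT levels of 0.81 for AT5G24240 to 4.39 for AT5G44440, so that these folds depend on the background level. The call of AT5G44440 was lost without WT LL array A or hy5 LL array B. HEMA2, a glutamyl-tRNA reductase gene, was the 1 chlorophyll synthesis gene of 6 called, at -1.17, over the list alone too. The photosystem list shifted up with no member called (median 0.25, camera adjusted p = 0.00728, lost with an estimated correlation at adjusted p = 0.262).

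In HL 302 probe sets were higher and 675 lower, 121 and 301 at least 2-fold. The named falls were AT5G23830 at -6.02, CSA1 at -5.38, AT3G44430 at -4.62 and LUL1 at -4.23, and the named rises AT1G10110 at 5.47, AT5G24240 at 5.29, AT4G08680 at 3.85 and AT1G50290 at 3.59. These falls ended at hy5 HL means of 1.14 for CSA1 to 2.71 for AT5G23830. Apart from AT1G50290, the rises started from WT HL means of 0.68 to 1.88. The folds at such levels depend on the background level. HEMA2 at -1.01 and CHLI2 at -0.39 were lower, 2 of 6 chlorophyll genes and 3 over the list alone, and SIR was higher by 0.46. The calls of CHLI2 and SIR were lost when any 1 of the 6 arrays was left out, without a filter and after median centring. Between the lights 98 rises and 304 falls were shared, 3.67 and 18.9 being the numbers for independent lists, from comparisons with no array in common. Of the 147 named genes lower in hy5 in both lights, 68 (46.3%) lie on chromosome 5, the chromosome that carries HY5, against 24% of the 8654 tested named genes. Of the 58 higher in both lights 12 (20.7%) do, and of the 10 at least 4-fold higher 4 (40%). In windows of 100 tested genes, with 1.7 lower genes per 100 over all and 3.28 on chromosome 5, the one from AT5G36270 held 13, the one that holds HY5 held 3, the one before it 6 and the next 0, and on other chromosomes the one from AT3G43430 held 7 and those from AT1G03830 and AT1G17850 held 5 each. The flavonoid genes CHIL, UGT78D2, DFR and UF3GT are on chromosome 5 and the other 4 on chromosomes 1, 3 and 4. The LL count of 655 was 1012 with array weights, 436 without hy5 LL array B, 320 at an adjusted p under 0.01 and 378 with the 2 groups fitted alone, and the HL count of 977 was 491 and 507 under the last 2 settings.

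**Figure D3:**
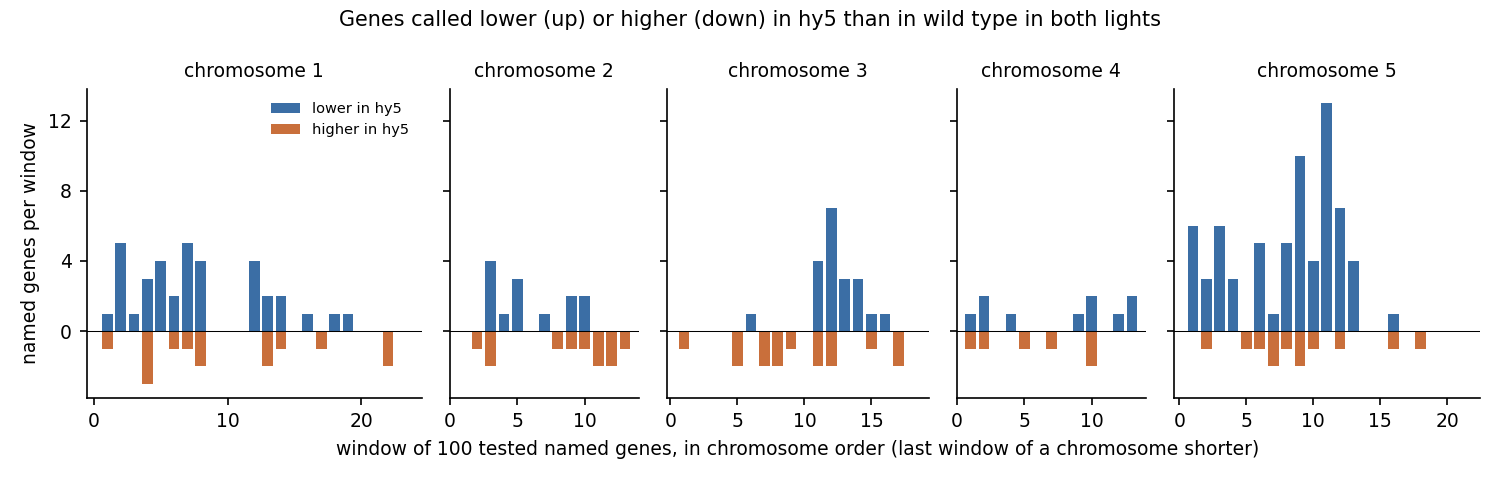
Named genes called lower (bars upward) and higher (bars downward) in hy5 than in WT in both lights, counted in windows of 100 tested named genes along each chromosome (x axis, window number in gene order). On chromosome 5 window 4 holds HY5 and had 3 lower genes, with 6 in window 3 and 0 in window 5.

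Within hy5, HL again raised flavonoid, heat shock and cold genes. Of 8 flavonoid enzymes 7 rose, over the list alone too, with CHIL up by 1.84, DFR by 1.61 and UF3GT by 1.60 (camera adjusted p = 1.27e-08, and adjusted p = 0.011 with an estimated correlation), and UGT78D1 at -0.05 was not called. All 6 heat shock genes rose, AT1G53540 by 5.03 (camera adjusted p = 2.36e-07, and adjusted p = 0.0135 with an estimated correlation), and the 3 cold genes rose (camera adjusted p = 9.56e-05, and adjusted p = 0.0318 with an estimated correlation). Of 6 chlorophyll synthesis genes 4 fell, PORB by 1.66 (camera adjusted p = 0.000811, and adjusted p = 0.011 with an estimated correlation), each of these counts being the same over the list alone. Of 7 photosystem and Calvin cycle genes 3 fell and 4 were called over the list alone (camera adjusted p = 0.00997, lost with an estimated correlation at adjusted p = 0.186). HYH rose by 2.67 ± 0.25. The root markers EXPA7 and EXPA18 fell by 0.89 and 0.87, calls lost without hy5 LL array B or hy5 HL array C, and LYC, a lycopene cyclase gene, fell by 0.55. In all 1408 probe sets rose and 1648 fell, 685 and 463 at least 2-fold, and the total of 3056 was 1748 at an adjusted p under 0.01.

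**Figure D4:**
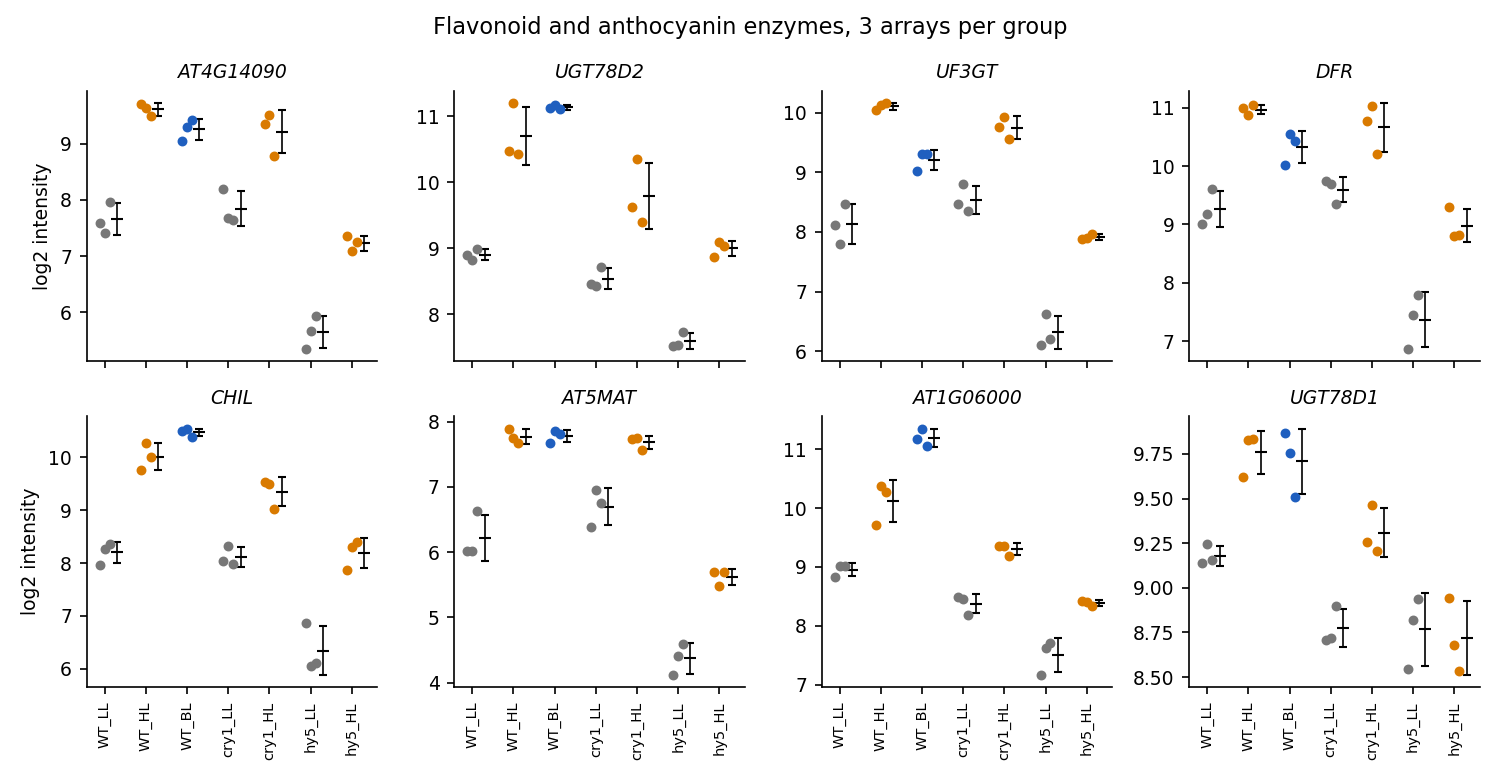
Log2 intensity of the 8 measured flavonoid and anthocyanin enzyme genes in each group (points are the 3 arrays, bars the mean and SD; grey LL, orange HL, blue BL; each panel has its own scale). All 8 rose from LL to HL in WT and were lower in hy5 HL than in WT HL.

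In the comparison of the HL responses of hy5 and WT, 833 probe sets had an unadjusted p under 0.05 in the limma fit. That is about the number this threshold gives on average without any difference. The difference of the responses was called for 1 probe set. It was the same probe set without a listed gene, at 4.86 ± 0.15 in hy5 in LL and 5.75 ± 0.14 in HL (SD, n = 3), with an interaction of -3.71 ± 0.36 (adjusted p = 0.000182). It was the 1 HY5-dependent gene among 992, and therefore the 1 gene dependent on both. That call held without each array in turn, the total being 4 without WT LL array C and 2 without WT HL array A, hy5 LL array C or hy5 HL array A or B. The flavonoid list had a median difference of response of -0.34 with no member called and 1 called when adjusted over the list alone (camera adjusted p = 0.00926, lost with an estimated correlation at adjusted p = 0.401). HYH had an interaction of 0.97 ± 0.35 (adjusted p = 0.854). On 497 rises and 179 falls chosen in cry1, the score rose by 3.54 in WT and 3.59 in hy5, a difference of 0.05 (exact permutation test, two-sided, p = 0.86 over 400 regroupings). On this score hy5 was lower than WT in both lights, at 2.04 ± 0.13 against 2.40 ± 0.13 in HL and -1.55 ± 0.11 against -1.14 ± 0.11 in LL (SD, n = 3; exact permutation p = 0.1 each), so that a lower level in HL does not by itself show a smaller response. Regroupings within a light mix in this difference between genotypes, so the exact permutation p = 0.86 does not show equal responses.

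Adjusted over the WT HL calls alone, the CRY1-dependent genes were 3 and the HY5-dependent genes 4, with 2 in common. All but 1 of them have no gene listed, and AT5G35970, named here after its values were seen, had a WT change of 1.09 and a hy5 interaction of -1.29 ± 0.25. The genotype effects of the mutants in HL overlapped in 18 rises and 53 falls. Independent lists would share 1.48 and 3.23, and simulated unchanged groups against the same WT arrays 24 and 34 among equally long top lists, so that part of this overlap may come from the shared controls (r = 0.313 against 0.504 in the simulation, covariance 0.0559 against 0.0431). The simulated comparisons had 0 calls each, so their top lists too are ranked noise.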

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

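The tests of the chromosomal position of genes lower in hy5, of array C of cry1 in HL and of whether only adjacent genes were hit in cry1 were chosen after these patterns were seen, and the others before. The wording of the lost segment in cry1 was narrowed to one that reaches the neighbours after its test was seen, and the tests of chromosome 5, of the chromosomal position of the genes under 4-fold, of the window that holds HY5, of the score without array C, of probe set numbers in cry1 and of the cry1 response of genes lower in hy5 were added after these values had been looked at.

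In 1 probe set without a listed gene the response to HL differed between mutant and wild type, by -2.52 log2 in cry1 and -3.71 in hy5. The flavonoid enzymes had median differences of response of -0.57 in cry1 and -0.34 in hy5, with none of the 8 called, and both list shifts were lost with an estimated correlation (adjusted p = 0.0884 and 0.401). Of 100 splits of the arrays by genotype within each light, the real one included, 13 gave at least the 1 call of the cry1 interaction. For hy5 14 of 100 did. The highest other splits called 1077 and 151 probe sets. Genotype was split anew in each light, so a genotype difference present in both lights can turn into an interaction in these splits. For the interactions, the dependent genes and their overlap, such counts can therefore neither exclude nor show chance. The 1 CRY1-dependent gene was reached in 11 of 100 splits (highest other 220), and the 1 HY5-dependent gene in 14 of 100 (highest other 76). Their overlap of 1 was reached in 4 of 100 splits (highest other 25), a share under 5%, but it is a single probe set from interactions that share the WT arrays, and it was lost in 14 of 18 fits without an array, without a filter, after a repeated quantile normalization, with the replicate block and at an adjusted p under 0.01. At least 1 list was called in 57 of 100 splits for the cry1 interaction (highest other 3) and 72 of 100 for hy5 (highest other 4). The split with 1077 calls put WT arrays A and B and cry1 array A in LL with WT array A and cry1 arrays A and C in HL, and points to a structure among the arrays beyond genotype.

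The comparisons of 3 with 3 arrays have 10 splits, too few for a share under 5%. The real split called the most probe sets in every such comparison but cry1 against WT in LL (1 of 10 splits). The numbers, with the highest of the other splits, were 2654 and 0 for WT HL vs LL, 3390 and 2 for WT BL vs LL, 3403 and 1 for WT HL vs BL, 1763 and 21 for cry1 HL vs LL, 3056 and 2 for hy5 HL vs LL, 655 and 1 for hy5 against WT in LL, and 158 and 1 for cry1 and 977 and 1 for hy5 against WT in HL. For cry1 against WT in LL, 2 of 10 splits called at least the 14 real ones. The highest called 145 and set WT arrays A and B with cry1 array A against the rest, which again points to a structure among the LL arrays, the division that the third principal component also shows. Real and highest other numbers of called lists were 4 and 3 for WT HL vs LL, 4 and 2 for WT HL vs BL, 5 and 3 for cry1 HL vs LL, 5 and 4 for hy5 HL vs LL and 3 and 2 for cry1 against WT in HL, each reached by 1 of 10 splits. They were 4 and 4 for WT BL vs LL (4 of 10 splits), 1 and 1 for cry1 against WT in LL (2 of 10), 2 and 2 for hy5 against WT in LL (4 of 10) and 1 and 3 for hy5 against WT in HL (9 of 10). The overlap of WT HL and BL calls, 1078, was reached by 1 of 100 splits (highest other 1067, which kept the real groups and used the HL arrays as the control). This leaves the shared LL arrays untested. With them alone, equally long top lists of simulated unchanged groups shared 387.1 rises and 592.2 falls, against 486 and 592 observed. Those simulated comparisons had 0 and 0.15 calls on average, so their lists are ranked noise and do not give the share of called genes that the controls explain.

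Of the 64 control probe sets, which no comparison used, 1 had a signal in hy5 alone. Its mean was 9.29 log2 in hy5 LL (9.11 to 9.41) and 6.87 in hy5 HL (6.57 to 7.11), whereas the 15 arrays of other groups lay between 0 and 4.79.

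Genes lower in hy5 in both lights lay in stretches of the genome. Of the 24 named genes at least 4-fold lower, 12 were on chromosome 5, above the 11 at the 99th percentile of 10000 random sets. Of the 10 at least 4-fold higher 4 were. The 24 formed 2 pairs within 10 tested genes of each other, no more than the 95th percentile of 2, so that close clusters were not shown. They are not excluded for the 37 probe sets of this size, since those without a listed gene could not be placed. The 123 genes lower by less than 4-fold formed 47 such pairs, against at most 41 in 10000 random sets, and 58 genes higher in hy5 formed 9, the 99th percentile. Of these 37 probe sets 13.5% rose in WT HL or BL against 12.2% of the others (Fisher's exact test p = 0.8). A higher share of light-induced genes was thus not shown, in a set too small to exclude one. This share and those that follow count rises in WT or cry1. They do not measure whether a rise is smaller in hy5, so they can neither show nor exclude lost light induction. The hy5 interaction, which measures that, was called for 1 of all kept probe sets. Of the 123 genes 30.1% rose against 11.3% (Fisher's exact test p = 2.09e-08), but the WT arrays entered both the choice of these genes and their response. The levels of the cry1 arrays did not choose these genes, but the residual variance of a probe set was shared by all 21 arrays. A probe set of small variance is called more easily in both, which may add to the shares. On the cry1 arrays 16.3% of the 123 rose in HL against 5.19% of the other tested named genes (Fisher's exact test p = 7.26e-06) and 6.9% of the 58 genes higher in hy5 (p = 0.102). Of the 37, 8.11% rose against 6.09% of the other kept probe sets (Fisher's exact test p = 0.492). Loss of HY5 activity at light-induced genes stays open. Chromosome segments from another accession, in which probes bind less well, may add to a true effect of the mutation, and both stay open. Whether such segments would include HY5 is not settled: against 1.7 lower genes per 100 tested and 3.28 on chromosome 5, the window of 100 that holds HY5 had 3, the one before it 6 and the next 0, with 13 from AT5G36270 and 7 on chromosome 3 from AT3G43430. On chromosome 5 the windows from AT5G46390 on held 0 or 1 lower genes each. Those before it, among them the one that holds HY5, held 0 to 13. This border was drawn after the counts were seen.

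Array C of cry1 in HL had a high light score of 0.466, between the LL arrays (-1.90 to -1.05) and the WT HL arrays (1.58 to 1.82). A growth light sample under a wrong label would score within the LL range, and the array lies above its top by more than the SD of 0.261 among LL arrays. Strong RNA degradation is argued against by 3 of 3 differences between 3′ and 5′ control probe sets inside the range of the other 20 arrays. Those ranges were wide, from 0.861 to 1.467 for actin and from -0.337 to 0.389 for ubiquitin, so that mild degradation is not excluded. The other cry1 HL arrays reached at most 1.301, below all WT HL arrays, but without array C the difference of the responses shrank from -0.50 to -0.23 (exact permutation p = 0.36). A smaller response of cry1 stays open, as do a weaker or shorter exposure of this sample and a mixture.

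Among probe sets with 1 listed gene, AT1G75280 and AT1G75300 were the largest falls in cry1 in both lights, and they are 1 place apart among tested genes. The 40 tested genes around them had a median difference of 0.013 from WT in LL, inside the -0.064 to 0.081 of 10000 random windows (5th to 95th percentile), and none was called in either light. This does not exclude a lost segment, because 3 of the 5 probe sets with a called fall of at least 4-fold in both lights have no listed gene and were not among those neighbours. The numbers of 2 of the 3 lie within 2 of that of AT1G75280 or AT1G75300, and 88.5% of 7074 pairs of named genes numbered so closely lie within 20 tested genes of each other. A lost segment with some of the genes around, a lesion of AT1G75280 and AT1G75300 alone and an effect of the cry1 mutation on their expression cannot be told apart, since 1 line was measured.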

How the results depend on the processing

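Log2 of the intensity plus 16 and the high light score without each array were chosen after the data were seen, and the other settings before. For results that moved the cause was not tested, except that a stricter threshold lowers a count by construction. At an adjusted p under 0.01 the called probe sets numbered 1496 for WT HL vs LL, 1635 for WT BL vs LL, 1602 for WT HL vs BL, 808 for cry1 HL vs LL, 1748 for hy5 HL vs LL, 7 and 320 for cry1 and hy5 against WT in LL, 47 and 491 in HL, and 538 for the overlap of WT HL and BL calls. The cry1 interaction, the CRY1-dependent genes and the overlap with HY5 fell to 0. For this interaction 702 probe sets had an unadjusted p under 0.05 in the limma fit, fewer than that threshold gives on average without any difference. With only the compared groups fitted the counts were 1691, 2011 and 1922 for WT HL vs LL, WT BL vs LL and WT HL vs BL, 466 for cry1 HL vs LL, 0 and 378 for cry1 and hy5 against WT in LL, 8 and 507 in HL, 0 for the cry1 interaction and CRY1-dependent genes, and 2 for the hy5 interaction and HY5-dependent genes.

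Without a filter cry1 differed from WT in HL in 101 probe sets and the overlap of dependent genes was 0. A filter at log2 7 gave 3 calls for the cry1 interaction and CRY1-dependent genes and 2 for hy5, and trend and robust priors 2 and 3. Array weights gave 61 and 1012 calls for cry1 and hy5 against WT in LL, 373 for cry1 in HL and 2 for the hy5 interaction. A repeated quantile normalization gave 0 for the cry1 interaction, the CRY1-dependent genes and the overlap. Log2 of the intensity plus 16 gave 2 for the hy5 interaction and HY5-dependent genes. Adjusting the interaction over the WT HL calls alone gave 3 CRY1- and 4 HY5-dependent genes. Selecting the 2-fold high light genes in hy5 gave 0 CRY1-dependent ones, and 1 when adjusted over that set alone. This choice leaves out the probe set called in the main fit, which rose in hy5 only from 4.86 to 5.75. Of 31 list calls with camera, 19 were left with an estimated correlation.

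The replicate letters share no more than a name: of 63 pairs of arrays with the same letter in different groups 8 had residuals correlated over 0.1 (range -0.206 to 0.195), and 9 of 21 arrays correlated best with an array of their own letter. With the replicate block the cry1 interaction, the CRY1-dependent genes and the overlap became 0 and the hy5 interaction 2, and no other count moved by over 1.5 times.

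Median centring kept the totals within 1.5 times but moved the split of the overlap of WT HL and BL calls from 486 rises and 592 falls to 643 and 397. Array medians moved by at most 0.163 log2 under it, and the splits of BL against LL and HL against BL moved as given with those comparisons. Leaving out 1 array at a time gave 2137 to 2778 calls for WT HL vs BL, 977 to 1977 for cry1 HL vs LL, 9 to 27 and 436 to 484 for cry1 and hy5 against WT in LL, and 46 to 169 for cry1 in HL. It gave 0 to 2 for the cry1 interaction and CRY1-dependent genes, 1 to 4 for the hy5 interaction, 1 to 2 for HY5-dependent genes and 0 to 1 for their overlap, and every other total stayed within 1.5 times. The 2-array group is then assumed to vary like the others. No called gene or list named in the text reversed. Counted once per gene, comparison and setting, named genes lost a call 137 times without an array and 143 times under other settings, gained one 3 and 13 times, and changed sign without a call 83 and 21 times. Gene lists lost a call 18 and 36 times, gained one 15 and 24 times and changed direction without a call 34 and 13 times. The others, 2177 and 3972 for genes and 557 and 972 for lists, stayed. Probe sets near the floor, with log2 under 5 in most arrays, limit what the folds can show.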

Other observations

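The gene families below were put together after the data were seen. In blue light 11 of 24 genes known to rise under low oxygen fell, among them AT1G33055 by 4.54, AT4G39675 by 4.08, AT1G19530 by 2.85 and AT4G10270 by 2.56 (camera adjusted p = 5.06e-05, lost with an estimated correlation at adjusted p = 0.23). In WT high light 1 rose and 1 fell, and 12 were higher in HL than in BL. The family was also lower in cry1 than in WT in LL, without blue light, by a median of -0.53 with no member called (camera adjusted p = 2.75e-05, lost at adjusted p = 0.183). Of 35 UDP-glycosyltransferases, which attach sugars to small molecules, 12 rose and 3 fell in cry1 HL (camera adjusted p = 5.01e-05, and adjusted p = 0.00653 with an estimated correlation). Several members had been seen among the largest changes before, and without the 6 named first the other 29 shifted up as well (7 rose and 3 fell, camera p = 0.0102 with an estimated correlation), in a test chosen after the family had been seen to shift. In WT HL 11 rose and 6 fell without a shift of the family (camera adjusted p = 0.102). The difference between these responses had no called member, and its shift (camera adjusted p = 0.0215) was lost with an estimated correlation (adjusted p = 0.208). In hy5 HL 13 rose and 6 fell (camera adjusted p = 0.215), and in WT BL 10 rose and 8 fell (camera adjusted p = 0.399). In cry1 against WT in LL the family had a median of -0.24 with no member called (camera adjusted p = 0.000716, and adjusted p = 0.0271 with an estimated correlation), and the 29 without those 6 a median of -0.22 (camera p = 0.0097 with an estimated correlation). This lower level and the rise in cry1 HL rest on the same cry1 LL arrays. Low values in those arrays would give both, so the results are not independent. Of 12 glutathione S-transferases 2 were higher in hy5 than in WT in HL and 4 when adjusted over the list alone (camera adjusted p = 0.000708, and adjusted p = 0.0143 with an estimated correlation).

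Few organelle genes were called. The 43 plastid-encoded photosynthesis genes had a median of 0.37 in hy5 against WT in LL with none called (camera adjusted p = 1.17e-06), lost with an estimated correlation (adjusted p = 0.238), and 0.38 in cry1 against WT in HL with none called and 9 called over the list alone (camera adjusted p = 1.16e-05, lost at adjusted p = 0.617). In hy5 HL 7 of them fell, without a shift (camera adjusted p = 0.49). The 22 plastid-encoded gene expression genes had a median of 0.46 in hy5 against WT in HL with none called (camera adjusted p = 0.000426, lost at adjusted p = 0.332). The 11 mitochondria-encoded respiratory genes had a median of 0.63 in cry1 against WT in LL with none called and 1 over the list alone (camera adjusted p = 0.00355, lost at adjusted p = 0.183), and in hy5 against WT in LL 1 was called. Of 22 cell wall loosening genes 6 were lower in HL than in BL, without a shift of the family (camera adjusted p = 0.0675), and of 7 auxin-responsive genes 4 rose in BL (camera adjusted p = 0.0111, lost at adjusted p = 0.0652).

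A hypothesis formed from the largest falls in blue light was that the low-oxygen response falls there as a group. Its test, chosen after those falls were seen, left out the 7 members seen first. The other 17 had a median of -0.84, 4 fell and none rose, but with an estimated correlation the camera p was 0.218 (0.012 with the preset correlation), so that the hypothesis was not borne out beyond the genes it came from.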
